A study of Homo sapiens with 9 samples.

How the data were processed

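RNA was measured in MCF-10A cells, an established line of non-tumorigenic human breast epithelial cells, that carried a doxycycline-inducible vector. Per the labels, doxycycline induced an empty vector control, ERK2 D319N or ERK2 Y261A, and RNA was taken after 7 days from 3 replicates of each of the 3 groups, 9 arrays in all. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted on columns and biotin-labelled cDNA was made with a whole-transcript kit for Affymetrix arrays.

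The deposited values are RMA signals on the log2 scale, made by the authors with Affymetrix Expression Console 1.4 and RMA, per the submitters' processing notes. RMA corrects background, brings all arrays to the same distribution of probe intensities and summarises the probes of a transcript cluster by median polish. The values ran from 1.08 to 14.45 with none missing, and no further normalization was applied. Median polish can return the same summary for several arrays. Here 14207 of 22411 genes (63.4%) had an identical value on at least 2 arrays of a group, and 5646 had it on all 3, so the spread of many genes may be understated. The array is a sample of hybridized probes with no count behind a value, and the number of arrays limits the precision. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

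The table held 70523 rows, of which 1529 were control probe sets. Of the 68994 other rows, 23781 had 1 gene symbol in the platform annotation, 1543 had several and 43670 had none. Rows with several symbols or none named no gene. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table for GRCh38.p14, which changed 306 of them, and 4 could not be matched. For the 528 genes with several rows, the row with the highest mean over all arrays stood for the gene. This left 22411 genes, 17151 of them protein-coding. The 23 background probe sets had a mean log2 signal of 4.85, and a level under this is read as near background. ERK2 itself and ZEB2 had no row with their symbol alone and were not analysed here, so the levels of the induced transcripts could not be checked.

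Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 9 arrays, so that the groups share an estimate of the spread with 6 residual degrees of freedom, and variances were moderated with eBayes, which found 1.23 prior degrees of freedom. The contrasts were D319N against vector, Y261A against vector and D319N against Y261A. P-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Errors given with a group mean are SDs over 3 arrays, and errors given with a difference are moderated standard errors. A gene was counted as set apart in a mutant when it passed against vector and against the other mutant in the same direction, and as changed alike when it passed in both mutants against vector in the same direction.

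Before the data were examined, 24 gene lists with 707 entries were fixed, of which 632 entries were found among the genes tested. The list of mitochondrially encoded genes had no member there, which left 23 lists and 69 tests over the 3 contrasts. Lists were tested two-sided with camera at a preset correlation of 0.01 between genes, adjusted over the 69 tests, and again with the correlation estimated from the data. Several lists share members. Also fixed beforehand were the rule for the genes named and the processing alternatives. The named genes are a fixed set (ERK1, DOCK10, FOXO1, RAC1, CDH1, CDH2, VIM, FN1, ZEB1, SNAI1 and SNAI2 among those measured), the 10 largest rises and 10 largest falls per contrast among called genes whose groups do not overlap on any array, and up to 4 members of each list with the smallest p per contrast. Every gene named for the size of its change therefore showed its direction on all 3 arrays against all 3 of the other group. A gene the rule named in a contrast may be given in another as well. Genes named outside this rule are said to be.

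The model was tested on simulated arrays with the real means and spreads of the 22411 genes, in which 50 genes at each of 4 folds differed between D319N and vector. It called 19 of 50 genes changed 1.2-fold, 40 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 50 of 50 changed 4-fold in the right direction, with 5 calls among the other genes. In a simulated Y261A contrast, all 3 lists shifted by 0.3 were called, with 1 other list. Genes were simulated without correlation or tied values, so this does not show how often camera errs where genes vary together. Alternatives left out each array in turn, added the replicate number as a block, centred or quantile-normalized the arrays again, filtered by level, used trended and robust moderation, array weights, all rows, means over rows, only the groups compared, a minimum fold of 1.5, other list tests, and 4 settings added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.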

Results

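Expression was profiled on 9 whole-transcript arrays from MCF-10A breast epithelial cells, 3 each for an empty vector, ERK2 D319N and ERK2 Y261A. ERK2 is the kinase at the end of the RAS-RAF-MEK cascade. The D319N substitution lies in its common docking domain and weakens binding of partners with a D motif, while Y261A lies in the pocket that binds the DEF motif of substrates. The study asks which genes depend on ERK2 and on each of these docking sites. No group expressing wild-type ERK2 was analysed here, so each mutant is compared with the vector and with the other mutant. Replicate arrays of a group correlated at 0.9977 to 0.9986 for vector, 0.9957 to 0.9977 for D319N and 0.9946 to 0.9982 for Y261A. The median SD of a gene was 0.036 in vector, 0.067 in D319N and 0.077 in Y261A. On the first principal component, with 63.4% of the variance, the D319N arrays lay at 16.34 to 27.99 and the other 6 arrays below 0. ERK1 (MAPK3) was level, at 7.96 in each of the 3 groups.

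Among the largest changes in D319N cells were the rise of a matrix gene and the falls of epithelial adhesion genes. FN1, which encodes the matrix protein fibronectin, rose from 7.41 ± 0.08 to 12.32 ± 0.02 (log2 signal, mean ± SD, n = 3), a 29.9-fold difference (log2 4.90 ± 0.05 SE, adjusted p = 2.16e-08). HSD17B2, an enzyme that inactivates estradiol, rose 23.4-fold (4.55 ± 0.06, adjusted p = 5.89e-08). EPCAM, an epithelial adhesion molecule, fell 6.34-fold from 8.88 ± 0.19 to 6.22 ± 0.19, and CDH1, which encodes E-cadherin, fell 2.60-fold (log2 -1.38 ± 0.07, adjusted p = 3.39e-05). In all, 3718 of 22411 genes passed, 2002 higher and 1716 lower, and 195 of them differed by at least 2-fold, 155 higher and 40 lower.

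Other large rises were those of IL1RL1, the receptor for interleukin-33 (log2 3.24), SLITRK6 (3.12), POSTN, a matrix protein (2.81), and FBXO32, a ubiquitin ligase subunit and FoxO target (2.56). They were followed by ITGA5, the alpha subunit of the fibronectin receptor (2.53), S1PR3, a sphingosine 1-phosphate receptor (2.46), CCDC80 (2.42) and DCN, which encodes decorin (2.42). IL1RL1, SLITRK6 and POSTN lay below the background mean in vector cells, so their folds are likely to be understated by the array. Large falls were those of SLC27A2, a fatty acid transporter (-2.53), FAT2, a protocadherin (-1.91), MAL2 (-1.70) and NUP210 (-1.56). They were followed by PSAT1, an enzyme of serine synthesis (-1.50), CXADR, a tight junction protein (-1.48), FGFBP1 (-1.42) and TACC2 (-1.40). The row named OCLNP1 fell by 1.73, and this pseudogene shares sequence with OCLN, the occludin gene, so its source is uncertain.

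**Figure D1:**
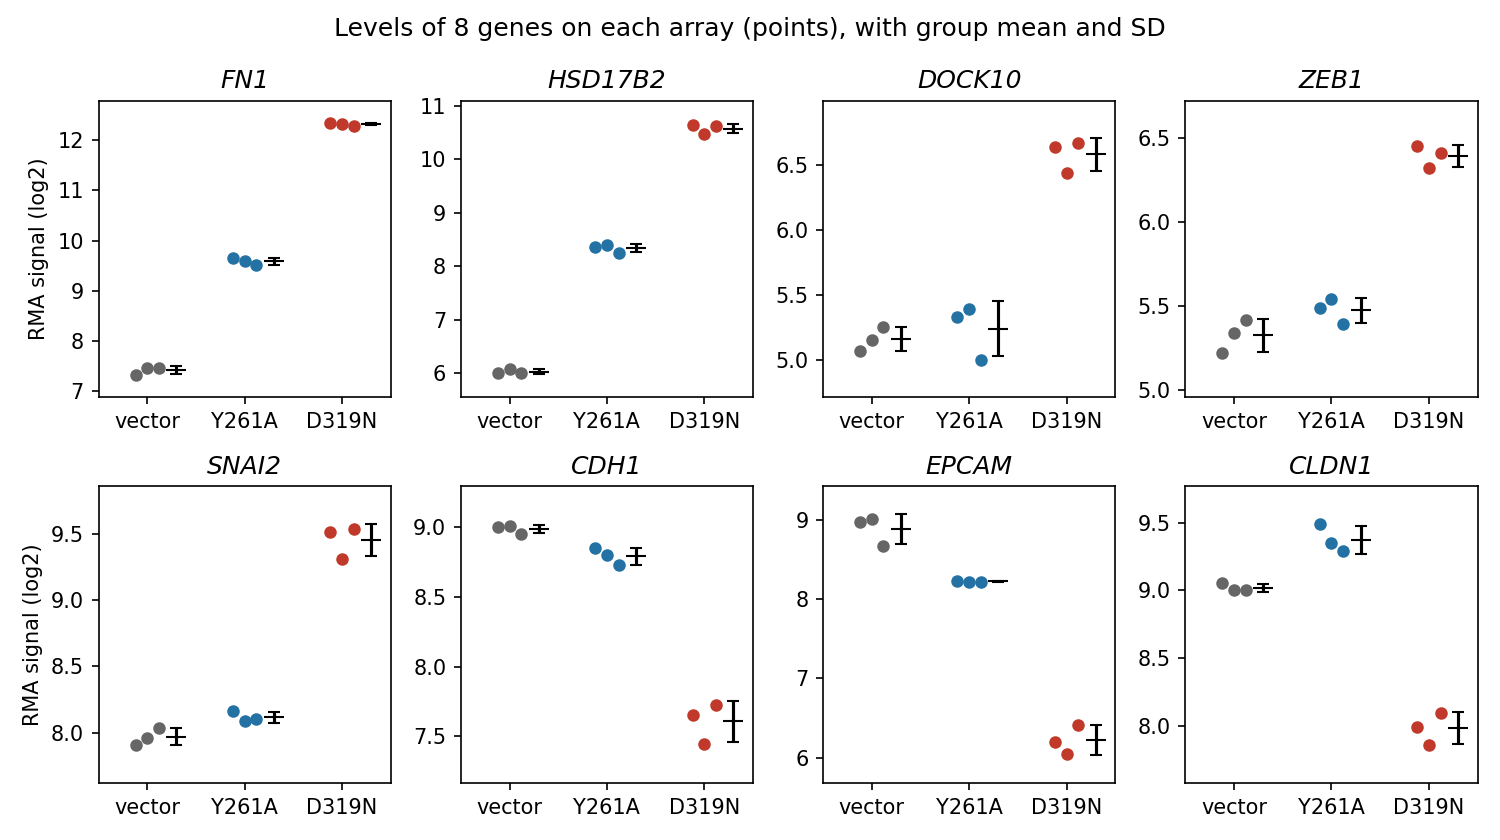
RMA signal (log2) of 8 genes on each array, with points for single arrays and a bar for the group mean with its SD (n = 3). FN1 and HSD17B2 lie between the vector and D319N levels in Y261A, while DOCK10 is at 6.58 in D319N and at 5.24 and 5.16 in Y261A and vector.

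The epithelial-mesenchymal lists moved in opposite directions in D319N cells. Of 43 epithelial junction genes, 22 fell and 2 rose (25 and 2 when adjusted over the list alone), among them MAL2, EPCAM, CDH1 and the splicing regulator ESRP1 (-1.11). This list was lower by camera (adjusted p = 1.57e-11), also with an estimated correlation (adjusted p = 0.0459). Of 47 mesenchymal genes, 26 rose (28 adjusted over the list alone), with the ecto-nucleotidase NT5E at 1.87, the collagen crosslinking enzyme LOX at 2.29, CDH2 or N-cadherin at 0.94 and VIM or vimentin at 0.67. This list was higher by camera (adjusted p = 2.31e-17), while the adjusted p was 0.0553 with an estimated correlation. The transcription factors SNAI2 (1.49 ± 0.06) and ZEB1 (1.07 ± 0.06), which repress epithelial genes, rose, and SNAI1 did not pass (-0.21 ± 0.10, adjusted p = 0.210). Among 20 keratin and lineage genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), including KRT5 (-1.29) and KRT15 (-0.52), and the list did not pass (adjusted p = 0.0939).

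In several lists of matrix and signalling genes, more members rose than fell. Of 26 TGF-beta targets, 18 rose (20 adjusted over the list alone), with LTBP1 at 1.55 and TGFBI at 1.10 (camera adjusted p = 7.79e-16, and adjusted p = 0.0850 with an estimated correlation). Of 24 matrix proteases and inhibitors, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with SERPINE2 at 1.85, CTSB at 1.53 and TIMP1 at 1.36 (adjusted p = 1.96e-08, and 0.0640 as the adjusted p with an estimated correlation). Of 20 basement membrane and hemidesmosome genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone), led by the integrin subunits ITGA2 (1.46) and ITGA3 (0.87) and the laminin gene LAMC1 (0.68). This list had an adjusted p of 7.95e-07 that became an adjusted p of 0.175 with an estimated correlation. Of 27 inflammatory cytokine and NF-kB genes, 13 rose (13 adjusted over the list alone), with the neutrophil chemokines CXCL8 at 2.10 and CXCL1 at 1.51 (adjusted p = 3.30e-07, and adjusted p = 0.120 with an estimated correlation). Of 14 EGFR family and ligand genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone). The ligand EREG rose by 2.28, while the ligand EPGN (-1.29) and the receptor inhibitor LRIG1 (-0.58) fell. The adjusted p of this list was 0.0215, and the adjusted p was 0.301 with an estimated correlation and 0.0845 with the arrays centred.

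Transcripts downstream of ERK rose in part. Of 22 ERK output genes, 12 rose and 4 fell (15 and 4 adjusted over the list alone), among them EGR1 (1.77), HMGA2 (1.21) and the feedback inhibitor SPRY4 (0.88). ETV1 (-0.38) fell (camera adjusted p = 3.30e-06, and adjusted p = 0.262 with an estimated correlation). Of 28 immediate early genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with JUNB at 1.35, CCN1 at 0.89 and MYC at -0.68 (adjusted p = 2.22e-04, and adjusted p = 0.221 with an estimated correlation). DOCK10 rose 2.68-fold (1.42 ± 0.11, adjusted p = 2.42e-04), and RAC1 did not pass (0.13 ± 0.05, adjusted p = 0.182). Of 40 DOCK and Rac pathway genes, 13 rose and 2 fell (15 and 3 adjusted over the list alone), with DOCK4 at 0.91 and the WAVE complex gene CYFIP2 at -1.04 (adjusted p = 0.00176, and adjusted p = 0.299 with an estimated correlation). FOXO1 rose 1.22-fold (0.29 ± 0.07, adjusted p = 0.0239), a call that passed in 4 of 9 fits without 1 array. It was lost without D319N replicate 1 or 3 or any vector array, with an adjusted p of at most 0.0841. Of 30 FoxO factors and targets, 13 rose and 2 fell (14 and 2 adjusted over the list alone), with IRS2 at 1.93, TXNIP at 1.01 and GADD45A at 0.95 (adjusted p = 3.39e-06, and adjusted p = 0.275 with an estimated correlation).

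In the cell cycle and heat shock lists, more members fell than rose in D319N cells. Of 47 cell cycle and DNA replication genes, 31 fell and 1 rose (38 and 2 adjusted over the list alone), with cyclin A2, CCNA2, at -0.74, the transcription factor MYBL2 at -0.74 and the mitotic kinase PLK1 at -0.71 (adjusted p = 4.10e-13, and adjusted p = 0.221 with an estimated correlation). Of 15 heat shock genes, 6 fell (8 fell and 1 rose when adjusted over the list alone), among them HSPA4L (-1.32) and the mitochondrial chaperonin genes HSPD1 (-0.60) and HSPE1 (-0.56). This list had an adjusted p of 0.00379 that became an adjusted p of 0.363 with an estimated correlation. Of 36 squamous differentiation genes, 3 fell and 1 rose (3 and 1 adjusted over the list alone), with ALOX15B at 1.69 and S100A9 at -0.50, and the adjusted p of 0.0232 became an adjusted p of 0.564 with an estimated correlation. Without D319N replicate 3 the squamous list did not pass (adjusted p = 0.0552). Members of further lists went both ways, and these lists did not pass. They were the interferon response (4 of 36 higher and 6 lower, adjusted p = 0.964), sterol synthesis (4 of 24 and 4, adjusted p = 0.377), glycolysis and hypoxia (7 of 29 and 6, adjusted p = 0.360), the unfolded protein and amino acid response (7 of 26 lower and 6 higher, adjusted p = 0.868) and p53 targets (3 of 22 each way, adjusted p = 0.946). Adjusted over the list alone, their counts of higher and lower members were 4 and 6, 8 and 6, 7 and 7, 7 and 8, and 5 and 4. Median and mean differed in sign for the interferon response (-0.01 and 0.02). OAS1 (-0.73), SREBF1 (-0.45), ANGPTL4 (1.90), ASNS (-0.55) and TP53I3 (0.63) were among the members that passed.

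Markers of other cell types gave the following values beside the mesenchymal list. Of 17 fibroblast and muscle markers, 3 rose (3 adjusted over the list alone), POSTN, DCN and the protease FAP (1.67), of which the mesenchymal list also holds all 3, and the list did not pass (adjusted p = 0.0632). That list passed with the arrays centred (adjusted p = 0.0330) or quantile-normalized (adjusted p = 0.0337), and without D319N replicate 1 (0.0428), D319N replicate 3 (0.0295) or vector replicate 3 (0.0279). Its median was -0.01 and its mean 0.39, so the shift rests on few members. The fibroblast collagen genes COL1A1 (0.00 ± 0.05) and COL1A2 (-0.07 ± 0.06), named outside the rule after the values were seen, did not pass. Of 23 leukocyte markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with the lysosomal protein gene CD68 at 1.57 and LAPTM5 at -0.86 (adjusted p = 0.220). None of 16 endothelial markers passed in limma, over all genes or over the list alone (1 at an unadjusted p under 0.05), and the list did not pass by camera (adjusted p = 0.906). As limits, the count of called genes was 7979 without D319N replicate 2 and Y261A replicate 3, a setting chosen after seeing the data, because these arrays deviate together from their groups. The share of calls that were higher, 53.8%, was 67.3% with the arrays centred and 44.2% without those 2 arrays, so neither direction prevails under every choice.

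FN1 and HSD17B2 also rose in Y261A cells, by less than in D319N cells. HSD17B2 rose 4.95-fold from 6.03 ± 0.05 to 8.33 ± 0.07 (log2 2.31 ± 0.06 SE, adjusted p = 7.90e-06). FN1 rose 4.51-fold from 7.41 ± 0.08 to 9.59 ± 0.07 (2.17 ± 0.05, adjusted p = 7.71e-06). The imprinted gene PEG10 fell 1.64-fold (-0.71 ± 0.03, adjusted p = 2.16e-04), and SORL1, a sorting receptor, fell 1.49-fold (-0.57 ± 0.02, adjusted p = 1.04e-04). In all, 79 genes passed, 31 higher and 48 lower, and 2 of them, HSD17B2 and FN1, differed by at least 2-fold. At an unadjusted p under 0.05 there were 2320 genes, and in 2993 genes (13.4%) the groups did not overlap. Chance gives 10% where no values are tied, and less with ties between groups, so 10% is an upper limit here.

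Further rises were those of AKAP12, a kinase scaffold (0.79), the cystine transporter SLC7A11 (0.67), monoamine oxidase MAOA (0.67), LTBP1 (0.63), NT5E (0.60), RPGR (0.60), the WNT inhibitor DKK1 (0.57) and DCN (0.56). Further falls were those of CD70 (-0.71), SYTL5 (-0.69, below the background mean in both groups), LAPTM5 (-0.68), PSAT1 (-0.64), the WNT inhibitor SFRP1 (-0.59), CXADR (-0.58), IFITM2 (-0.56) and EHF (-0.56). None of the fixed genes of adhesion and motility besides FN1 passed. DOCK10 differed by 0.08 ± 0.11 (adjusted p = 0.798), FOXO1 by -0.23 ± 0.07 (adjusted p = 0.307) and RAC1 by -0.10 ± 0.05 (adjusted p = 0.624), which does not show that they are equal. CDH1 differed by -0.19 ± 0.07 (adjusted p = 0.405), CDH2 by -0.05, VIM by -0.15, ZEB1 by 0.15, SNAI2 by 0.15 and SNAI1 by -0.12.

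Gene lists were called in Y261A cells with few members past the gene threshold, and none of these list calls held with an estimated correlation. Mixed groupings of the same 6 arrays called up to 10 lists, against 12 for the real groups. Of 47 mesenchymal genes, 4 rose, FN1, NT5E, DCN and FAP (10 adjusted over the list alone), with an adjusted p of 1.09e-05 and an adjusted p of 0.177 with an estimated correlation. Of 43 epithelial junction genes, EHF fell (10 fell and 1 rose adjusted over the list alone), with an adjusted p of 0.00247 and an adjusted p of 0.175 with an estimated correlation. No member of the cell cycle list passed over all genes in limma (21 of 47 at an unadjusted p under 0.05), and 14 fell when adjusted over the list alone. The median was -0.14 (adjusted p = 1.70e-12, and adjusted p = 0.221 with an estimated correlation). TGF-beta targets (2 of 26 higher, 10 adjusted over the list alone, adjusted p = 3.90e-10) and inflammatory genes (1 of 27 higher, 9 adjusted over the list alone, adjusted p = 1.32e-06) shifted up, with an adjusted p of 0.137 and 0.124 with an estimated correlation. Basement membrane genes (median 0.05, 1 member higher adjusted over the list alone, adjusted p = 1.48e-04), matrix proteases (0.04, 4 members, adjusted p = 2.22e-04) and fibroblast and muscle markers (0.05, 3 members, adjusted p = 2.13e-04) shifted up as well. These calls had an adjusted p of 0.221, 0.161 and 0.210 with an estimated correlation. Heat shock genes (median -0.14, 7 lower adjusted over the list alone, adjusted p = 5.40e-06), sterol synthesis (-0.08, 4 lower, adjusted p = 3.31e-06), p53 targets (-0.08, 1 lower, adjusted p = 7.95e-06) and the unfolded protein and amino acid response (-0.04, 6 lower and 1 higher, adjusted p = 0.00600) shifted down. These calls had an adjusted p of 0.221, 0.299, 0.221 and 0.221 with an estimated correlation. Quantile normalization lost the calls of epithelial junctions (adjusted p = 0.619), sterol synthesis (0.172), heat shock (0.0985) and the unfolded protein and amino acid response (0.112). The last of these was also lost without Y261A replicate 3 (adjusted p = 0.0521).

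ERK output genes did not pass as a list in Y261A cells (median -0.06, adjusted p = 0.0933), and none of the 22 passed singly in limma (5 at an unadjusted p under 0.05), with 1 higher and 2 lower adjusted over the list alone. The list passed without vector replicate 1 (adjusted p = 0.0488) or Y261A replicate 1 (adjusted p = 0.0216), with lower levels in Y261A. The immediate early genes (adjusted p = 0.458), the DOCK and Rac pathway (adjusted p = 0.0617), the FoxO list (adjusted p = 0.227) and keratins (adjusted p = 0.517) did not pass either. Without Y261A replicate 1 the DOCK and Rac pathway passed as lower (adjusted p = 0.0113), and without Y261A replicate 3 the FoxO list passed as higher (adjusted p = 0.00118). Squamous genes (adjusted p = 0.237), the EGFR family (adjusted p = 0.272), interferon genes (adjusted p = 0.602), glycolysis and hypoxia (adjusted p = 0.386, but higher at 0.0425 with quantile normalization), leukocyte markers (adjusted p = 0.710) and endothelial markers (adjusted p = 0.128) did not pass. As limits, the count of 79 was 27 with centring (25.9% higher in place of 39.2%) and 122 with quantile normalization (54.9% higher), and 24 when tied genes were given at least the spread of genes without ties, a test chosen after seeing the data. It was 41 without D319N replicate 1, 133 without D319N replicate 2, 15 and 12 without vector replicates 1 and 2, 9 without Y261A replicate 1 or 2, and 46 without Y261A replicate 3. Of the 27 named genes called here, 7 passed in all 9 of these fits (FN1, HSD17B2, NT5E, PEG10, SORL1, CD70 and CYFIP2).

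The mutants were then compared directly, which tests whether D319N and Y261A cells differ. The levels of the induced ERK2 forms could not be checked, so an effect of the substitution cannot be told apart from one of its level. D319N cells had 6.86-fold more IL1RL1 than Y261A cells (log2 2.78 ± 0.05 SE), 6.63-fold more FN1 (2.73 ± 0.05, adjusted p = 1.10e-06) and 5.57-fold more LOX (2.48 ± 0.06, adjusted p = 3.25e-06). EPCAM was 4.01-fold lower (6.22 ± 0.19 against 8.22 ± 0.01, adjusted p = 9.79e-05) and CDH1 2.27-fold lower (-1.19 ± 0.07, adjusted p = 1.11e-04). In all, 3281 genes passed, 2224 higher and 1057 lower in D319N, and 147 of them differed by at least 2-fold, 135 higher. The spread was pooled with the vector arrays, whose median SD was lowest (0.036 against 0.067 in D319N and 0.077 in Y261A). A fit of only the D319N and Y261A arrays, with fewer residual degrees of freedom, gave 1933 genes. A total of 2616 genes were set apart in D319N, 1766 higher and 850 lower, and 8 in Y261A.

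Other genes far higher in D319N than in Y261A were SLITRK6 (2.58), POSTN (2.43), the secreted hormone STC1 (2.35), FBXO32 (2.26), HSD17B2 (2.24), S1PR3 (2.18) and EREG (2.11). Lower were SLC27A2 (-1.80), FAT2 (-1.70), OCLNP1 (-1.53), CLDN1 (-1.39), MAL2 (-1.33), NUP210 (-1.13), MPZL2 (-1.10) and the desmosomal cadherin DSG3 (-1.07). CLDN1, a tight junction claudin, was at 7.98 in D319N, 9.02 in vector and 9.37 in Y261A. DOCK10 was 2.53-fold higher in D319N (1.34 ± 0.11, adjusted p = 4.68e-04), and FOXO1 (0.52 ± 0.07, adjusted p = 0.00276), RAC1 (0.22 ± 0.05, adjusted p = 0.0349), CDH2 (0.99), VIM (0.81), ZEB1 (0.92) and SNAI2 (1.34) were higher too. The RAC1 call passed in 2 of 9 fits without 1 array, those without D319N replicate 2 or Y261A replicate 1, and reached an adjusted p of 0.117 without D319N replicate 1. SNAI1 did not pass (-0.09 ± 0.10, adjusted p = 0.513).

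**Figure D2:**
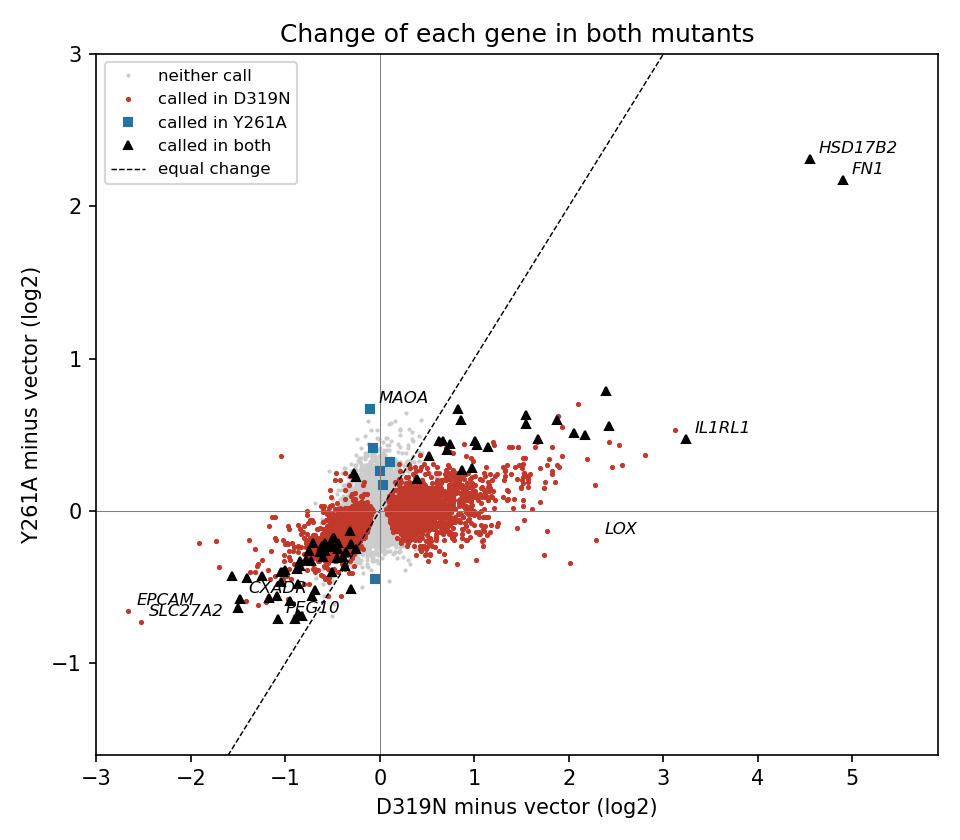
Change of each gene in D319N (horizontal axis) and in Y261A (vertical axis) against vector, in log2 units, each point a gene. FN1 lies at 4.90 and 2.17 and HSD17B2 at 4.55 and 2.31, both under the dashed line of equal change, and PEG10 lies at -1.08 and -0.71.

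By list, the direct comparison gave 14 calls. Epithelial junction genes were lower in D319N (21 of 43 lower and 3 higher, 28 and 3 adjusted over the list alone, adjusted p = 1.91e-10, and adjusted p = 0.0459 with an estimated correlation). Mesenchymal genes were higher (28 of 47, 29 higher and 3 lower adjusted over the list alone, adjusted p = 2.23e-14, and adjusted p = 0.0640 with an estimated correlation). ERK output genes (12 of 22 higher and 2 lower, 15 and 4 adjusted over the list alone, adjusted p = 9.25e-07), with EGR1 at 1.90 and the pleckstrin-like gene PHLDA1 at 0.88, had an adjusted p of 0.240 with an estimated correlation. The DOCK and Rac pathway (16 of 40 higher and 1 lower, 19 and 2 adjusted over the list alone, adjusted p = 7.31e-05) and the FoxO list (14 of 30 higher and 2 lower, 16 and 4 adjusted over the list alone, adjusted p = 1.84e-06) had an adjusted p of 0.221 and 0.263 with an estimated correlation. TGF-beta targets (16 of 26 higher and 1 lower, 20 and 1 adjusted over the list alone, adjusted p = 1.07e-11) and matrix proteases (11 of 24 higher, 11 and 1 lower adjusted over the list alone, adjusted p = 1.32e-06) were higher, with an adjusted p of 0.120 and 0.0903 with an estimated correlation. Inflammatory genes (12 of 27 higher, 14 adjusted over the list alone, adjusted p = 5.25e-05), immediate early genes (11 of 28 higher and 1 lower, 15 and 1 adjusted over the list alone, adjusted p = 5.25e-05) and basement membrane genes (10 of 20 higher, 10 and 3 lower adjusted over the list alone, adjusted p = 3.62e-04) were higher. These calls had an adjusted p of 0.175, 0.215 and 0.246 with an estimated correlation. Cell cycle genes (13 of 47 lower, 23 adjusted over the list alone, adjusted p = 1.12e-06) and squamous genes (4 of 36 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.00326) were lower, with an adjusted p of 0.368 and 0.469 with an estimated correlation. Sterol synthesis (8 of 24 higher and 1 lower, 11 and 2 adjusted over the list alone, adjusted p = 4.84e-04) and p53 targets (6 of 22 higher, 7 and 1 lower adjusted over the list alone, adjusted p = 0.0320) were higher, with an adjusted p of 0.451 and 0.518 with an estimated correlation. Quantile normalization lost both calls (adjusted p = 0.0686 and 0.377), and the p53 call was also lost without D319N replicate 1 (0.0657), D319N replicate 3 (0.0606), vector replicate 3 (0.0647) or Y261A replicate 3 (0.0761). Keratins (adjusted p = 0.0771) and glycolysis and hypoxia (adjusted p = 0.0564) did not pass. Keratins passed as lower without D319N replicate 3 (0.0416) or with quantile normalization (0.0220). Glycolysis and hypoxia passed as higher without D319N replicate 2 (0.0295) or Y261A replicate 1 (0.0208) or with the arrays centred (0.0484). The EGFR family (adjusted p = 0.159), interferon genes (0.401), the unfolded protein and amino acid response (0.568), heat shock (0.272, but lower at 0.0220 with quantile normalization), leukocyte (0.210), endothelial (0.381) and fibroblast and muscle markers (0.386) did not pass.

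**Figure D3:**
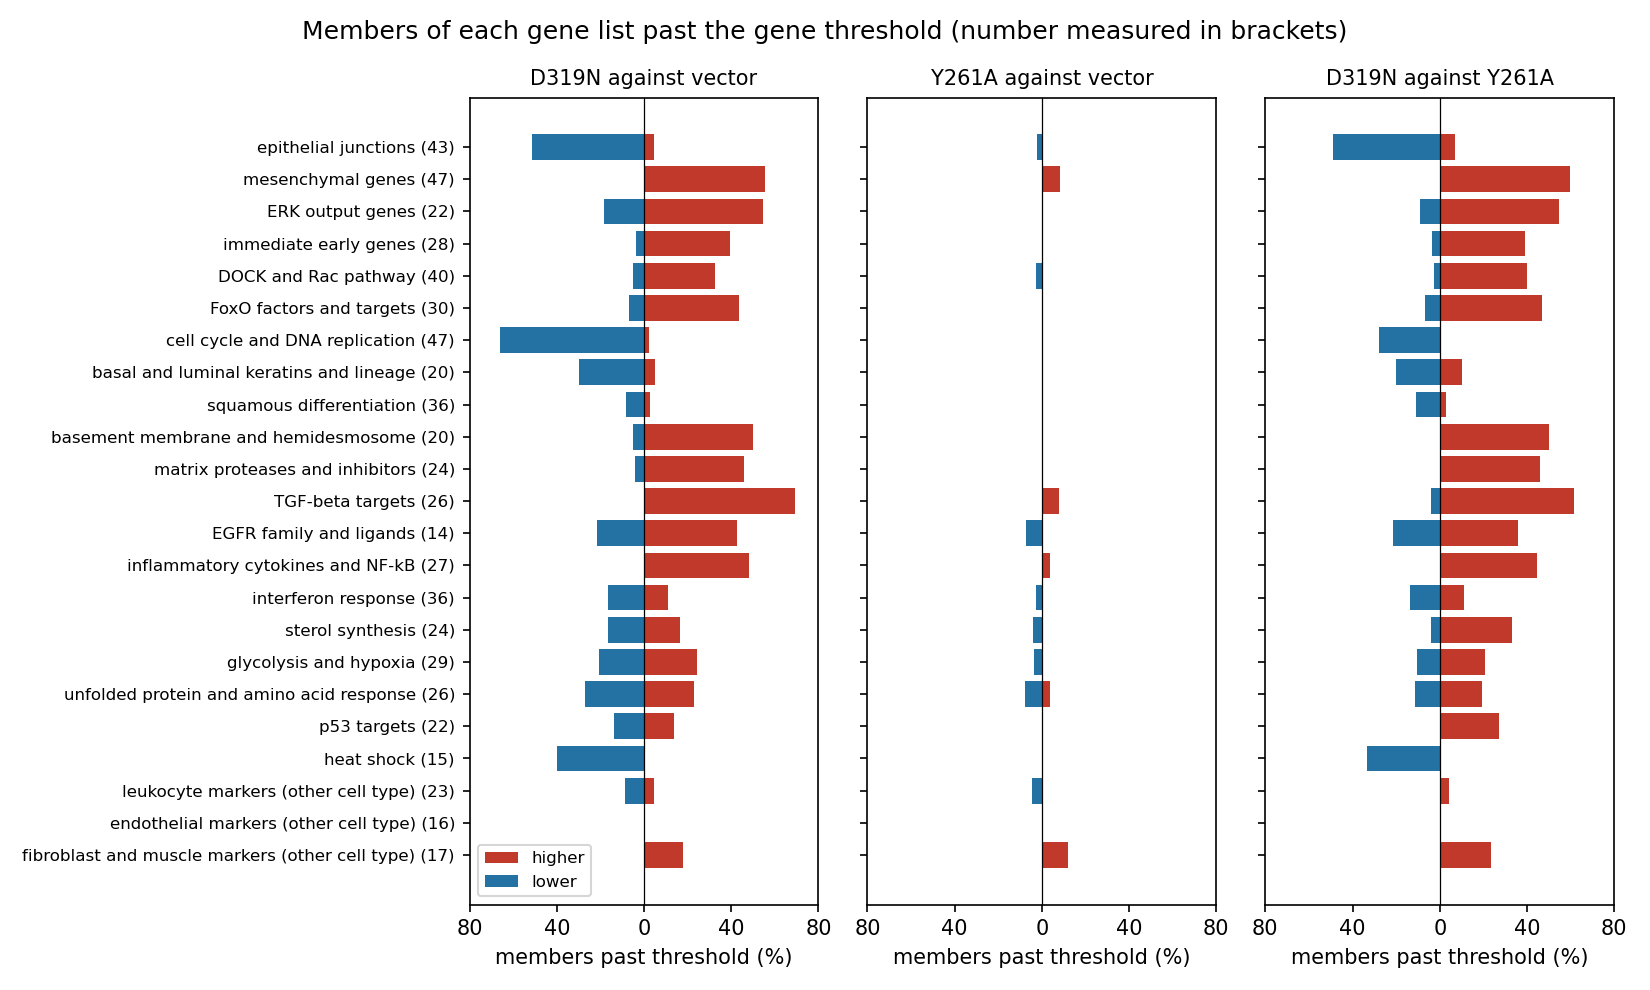
Share of measured members of 23 gene lists (percent, list size in brackets) past the gene threshold in each comparison, higher members to the right and lower members to the left. In D319N against vector the bars reach 18 of 26 TGF-beta targets higher and 31 of 47 cell cycle genes lower, while no list in Y261A against vector has more than 4 members past the threshold.

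The 8 genes set apart in Y261A, named outside the rule for their small number, were MAOA (0.67 against vector), the arginase gene ARG2 (0.41), GCLC, a subunit of the enzyme that starts glutathione synthesis (0.32), FRMPD4 (0.26, below the background mean in all groups) and FUZ (0.17), and the keratin pseudogenes KRT17P1 (0.25) and KRT17P2 (0.22), which rose. KCNIP3 fell (-0.45). They were picked after the values were seen. The pseudogenes are near copies of KRT17 and their signals may not be told apart from it. The count of 3281 was 1941 without D319N replicate 1 and 5302 without D319N replicate 2, and the 2616 genes set apart in D319N were 1678 without D319N replicate 1. The 8 set apart in Y261A were 2 and 13 without D319N replicates 1 and 2, 4 without vector replicate 3, and 0 without vector replicate 1 or 2 or Y261A replicate 1 or 2. Without D319N replicate 2 and Y261A replicate 3 together the 3281 genes were 6259, with 51.6% higher in place of 67.8%, and centring the arrays put 85.5% higher. For the genes set apart in D319N the share was 52.0% without these 2 arrays and 84.3% with centring, in place of 67.5%, and array weights put less than 50% higher in both (41.7% and 42.4%). Those weights leaned mostly on replicate 1 of each mutant, at 5.23 for D319N and 3.20 for Y261A.

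Both mutants were also compared for the genes they share. Of the 79 genes called in Y261A, 71 were called in D319N in the same direction, 24 higher and 47 lower, among them HSD17B2, FN1, NT5E, DCN, LTBP1, PEG10, SORL1, PSAT1 and CXADR. Lists drawn independently from 22411 genes would share 2.77 higher and 3.68 lower genes, and 20 simulations of unchanged groups against common vector arrays shared at most 1. Unchanged groups leave few calls to share, so these simulations are no reference for the 71. A simulation with D319N changed and Y261A unchanged was not run. Over all genes, which are not independent replicates, the fold changes correlated at Pearson's r = 0.362 and Spearman's rho = 0.155, against a mean r of 0.503 in the simulations. The covariance was 0.00951 against 0.00318 simulated, a difference of 0.00634. The simulations gave the 3 groups the same spread for a gene. In the data the median SD was 0.036 in vector, 0.067 in D319N and 0.077 in Y261A. Neither simulated value is therefore a reference for these arrays. With separate vector arrays for the comparisons, r ran from 0.176 to 0.299 over 6 assignments, and part of the overlap may come from the shared controls. Over the genes called in D319N, the slope of the Y261A change on the D319N change was 0.18. With quantile normalization 52.9% of the genes changed alike were higher, in place of 33.8%. The 71 genes were 39 without D319N replicate 1 or Y261A replicate 3, 120 without D319N replicate 2, 15 and 12 without vector replicates 1 and 2, and 9 without Y261A replicate 1 or 2.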

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

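The tests of D319N cells in the Y261A cultures, of exchanged labels, of hybridization, of signal range and of tied values were chosen after the result had been seen, while the splits of the arrays and the separate vector arrays were set before.

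The effects of the mutants against the same vector arrays differed by a test of the difference itself. It gave 3281 genes between D319N and Y261A, with 2616 genes set apart in D319N and 8 in Y261A. By list, the median difference of D319N minus Y261A was -0.21 for epithelial junctions, 0.47 for mesenchymal genes, 0.39 for ERK output genes, 0.14 for immediate early genes, 0.14 for the DOCK and Rac pathway, 0.27 for FoxO factors and targets, -0.17 for the cell cycle, -0.13 for squamous differentiation, 0.15 for basement membrane, 0.12 for matrix proteases, 0.25 for TGF-beta targets, 0.17 for inflammatory genes, 0.16 for sterol synthesis and 0.04 for p53 targets. With an estimated correlation, epithelial junctions was the list that kept its call. In rows without a gene name, a signal no comparison of genes used, 2582 of 43670 passed in D319N against vector when all rows were tested together, 1018 higher and 1564 lower.

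Regrouping the 6 arrays of a comparison gave far fewer gene calls than the real groups, but nearly as many list calls. The splits were too few to reach a share under 0.05 for a pair of groups. Of the 10 splits of the 6 arrays, 1 gave as many genes as the real split in each comparison, namely the real split itself. It gave 3718 genes for D319N against vector where the highest other split gave 0, 79 for Y261A against vector where the highest other gave 0, and 3281 for D319N against Y261A where the highest other gave 2. For called lists the real splits gave 14, 12 and 14 and the highest other splits 13, 10 and 11, again with 1 of the 10 splits as large in each. Mixed groups can keep part of a real difference, so this gives no rate of false list calls. The number of called lists therefore hardly sets the real groups apart from mixed ones. Of 100 drawn splits of the 9 arrays, 1 gave as many as 2616 genes set apart (highest other 2429), 4 gave as many as the 8 set apart in Y261A (highest other 2390) and 2 gave as many as 71 changed alike (highest other 2253). For the 2616 genes the splits show that the D319N arrays lie apart from the other 6, and do not exclude chance differences between cultures. For the 8 and the 71 the splits decide nothing. Splits that put D319N arrays in several groups gave 0 genes, as they widen the spread. Those that kept them together gave up to 2429 for the first count, and up to 2390 and 2253 under another name for the others. This points to the distance of the D319N arrays from the other 6.

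The first pattern is that most genes called in Y261A changed the same way in D319N, at a lower size. If noise of single vector arrays alone made the correlation over all genes, separate vector arrays would give r near 0. The lowest r was 0.176, which argues against such noise as its only source. The vector arrays may come from the same culture, and an offset common to all of them would remain after they are separated. The deviation that D319N replicate 2 and Y261A replicate 3 share (r = 0.60) enters both mutant means and would remain as well. Its part in the correlation was not measured. The test therefore does not decide whether shared controls made this pattern. D319N cells in the Y261A cultures would give every gene the same share of its D319N change, but at least 33 of the 70 genes changed alike besides FN1 differed from this (p adjusted over 3717 genes called in D319N, under 0.05) at every share from 1% to 50%, and 63 did at 12%, near the share FN1 gives. The 70 were picked for passing in Y261A, which favours genes beyond the prediction, so their counts decide nothing. Of all 3717 genes, not picked by their Y261A values, 186 (5.00%) differed at 12%. At 9%, the share where fewest did, 176 (4.74%) differed. For these few genes such cells are argued against as the only cause, and not for the others. A weaker action or a lower level of Y261A stays open and was not tested, and the overlap may still come from shared controls, in part or in full.

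The second pattern is that D319N replicate 2 and Y261A replicate 3 deviate from their groups together (r = 0.60 between their deviations), and that without both the counts of called genes rise to 7979, 157 and 6259. The data argue against exchanged labels. On a scale with the other Y261A arrays at 0 and the other D319N arrays at 1, D319N replicate 2 had a median position of 0.87 and Y261A replicate 3 of -0.09 over the 100 genes that differ most. Weaker hybridization was predicted to lower the 4 hybridization controls on both arrays. D319N replicate 2 was 0.09 above the other D319N arrays, and Y261A replicate 3 was 0.13 below its group. The controls were read after RMA had brought all arrays to the same distribution, which can hide a general loss of signal, so they do not decide this. A candidate explanation is a compressed signal range, in which bright genes lose and middling genes gain. The median deviation of the brightest 10% of genes was -0.12 on Y261A replicate 3 and -0.10 on D319N replicate 2, with the fifth of 10 classes by level at 0.10 and 0.06, so the range may be compressed on both. No biological explanation was tested.

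The third pattern is the tied values left by the summarisation, on 63.4% of genes. Tied genes were called less often than others, 10.1% against 27.9% in D319N against vector and 0.282% against 0.475% in Y261A against vector. When tied genes were given at least the median spread of genes without ties at their level, 49.3% of their 1431 calls in D319N against vector and 7.50% of their 40 calls in Y261A against vector remained. The same rise in spread kept 76.9% and 35.9% of the calls on genes without ties, so an effect of ties cannot be told apart from that of picking called genes for a low spread. No biological explanation was tested.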

How the results depend on the processing

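The settings that left out 2 arrays or tied genes, added a background covariate or set a floor to the spread were chosen after seeing the data. With few arrays and tied values, the spread of each gene is a limit, and levels near the background mean of 4.85 limit folds. No gene called in the reported fit was called in the opposite direction under any setting that tested the same genes. The cause was not tested except where fewer genes or arrays entered.

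The same replicate numbers do not pair samples. Deviations of same-numbered arrays correlated at -0.45 to 0.21, with 2 of 9 pairs over 0.1. With the replicate block, counts were 3063 for D319N against vector, 2490 for D319N against Y261A and 2079 set apart in D319N, and 13 for Y261A against vector, 1 set apart in Y261A and 12 changed alike.

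Counts are given in the order D319N against vector (3718), Y261A against vector (79), D319N against Y261A (3281), set apart in D319N (2616), set apart in Y261A (8) and changed alike (71). Array weights gave 11631, 988, 10403, 9292, 183 and 814, with 38.3%, 37.3%, 41.7%, 42.4%, 53.6% and 33.8% higher. The weights of replicates 1 to 3 were 5.23, 0.262 and 0.430 in D319N and 3.20, 1.19 and 0.124 in Y261A. The weighted means of the mutants thus rest mostly on replicate 1. A fold of at least 1.5 gave 692, 14, 570, 477, 1 and 13. Leaving out D319N replicate 2 and Y261A replicate 3 gave 7979, 157, 6259, 5875, 19 and 140. The share of higher calls in D319N against vector was also below 50% with all rows (47.7%), the background covariate (47.6%), tied genes left out (47.2%) and a floor at the median spread (49.1%). Over fits without 1 array, counts ran from 2523 to 4572, 9 to 133, 1941 to 5302, 1678 to 3667, 0 to 13 and 9 to 120. Centred arrays gave 27, 1 and 26 for the second, the fifth and the sixth, with 67.3%, 25.9%, 85.5% and 84.3% higher in the first to the fourth (main 53.8%, 39.2%, 67.8% and 67.5%). Quantile normalization gave 122 (54.9% higher) and 18 (66.7% higher, main 87.5%) for the second and the fifth, and 52.9% higher for the sixth (main 33.8%). All rows gave 5887, 26, 1 and 26 for the first, the second, the fifth and the sixth. Genes at or above the median level gave 17 and genes at log2 5 or more gave 15 set apart in Y261A. Without tied genes the second, the fifth and the sixth were 39, 2 and 37. A floor at the median spread gave 460, 148 and 277 for them. Here the moderation was estimated again after the floor was set, while the raised spread of tied genes kept the moderation of the reported fit. The background covariate gave 1927, and the fit of only the groups compared 1933, for the third.

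List calls numbered 40, against 2 with an estimated correlation. Fry, which tests the members against no change and not against other genes, called 44 by direction (34 with the reported call and direction) and 66 in its mixed form, which counts changes either way. With an estimated correlation, adjusted p was 0.0553 and 0.262 for mesenchymal and ERK output genes in D319N against vector, 0.175 and 0.177 for epithelial junctions and mesenchymal genes in Y261A against vector, and 0.0640 and 0.240 for mesenchymal and ERK output genes in D319N against Y261A. Epithelial junctions in Y261A against vector had 0.619 with quantile normalization and 0.0505 among genes at or above the median level. ERK output genes in Y261A against vector passed without vector replicate 1 (0.0488) and without Y261A replicate 1 (0.0216), and in fry's mixed test (2.76e-04). Over the fits without 1 array its adjusted p ran from 0.0216 to 0.812. Glycolysis and hypoxia in Y261A against vector turned upward and passed with quantile normalization (0.0425). The correlation of fold changes (0.362) was 0.703 among called genes and 0.247 to 0.539 without 1 array. Of the named genes called, 93 of 98, 7 of 27 and 90 of 98 passed in all 9 fits without 1 array.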

Other observations

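The gene families in this part and the test of NRF2 targets were chosen after their values had been seen, so they are hypotheses and not independent tests.

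Some integrin subunits, parts of the receptors that bind cells to matrix, rose in D319N cells besides those already named. Of 26 measured, 10 rose against vector, among them ITGAV (1.53 ± 0.05), ITGB6 (0.74 ± 0.05), ITGB1 (0.65 ± 0.05), ITGB8 (0.52 ± 0.07), ITGB5 (0.50 ± 0.08) and ITGB3 (0.47 ± 0.04), while the median of the family was 0.04. In Y261A cells ITGB6 rose (0.44, adjusted p = 0.0250), where 0 of the 26 passed with the arrays centred and 6 rose with quantile normalization, and 9 of the 26 were higher in D319N than in Y261A, with 10 higher and 1 lower under quantile normalization. The counts in D319N against vector were 10 and 11 higher with the arrays centred or quantile-normalized. Some clustered histone genes, which cells express while copying DNA, fell beside the cell cycle list. Of 32 measured, 14 fell in D319N against vector, with H1-4 at -1.20 ± 0.12, H2BC14 at -0.97 ± 0.09 and H2BC10 at -0.84 ± 0.13, and the median was -0.27. In Y261A the median was -0.21 and H1-1 passed (-0.36, adjusted p = 0.0353), a call lost when the arrays were centred. With the arrays centred 11 histone genes fell and 1 rose in D319N, and with quantile normalization 14 fell and 1 rose.

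The steroid-metabolising enzymes AKR1C1 and AKR1C2, near copies whose probes may share signal, rose in both mutants, AKR1C1 by 0.71 in D319N and 0.40 in Y261A and AKR1C2 by 0.67 and 0.46. With GCLC and SLC7A11 also higher in Y261A, a candidate explanation was the oxidative stress factor NRF2, whose targets include these genes. The 15 other NRF2 targets measured had a median of -0.04 in Y261A against vector with an SD of 0.12 over members, where the smallest rise of the 4 genes was 0.32, and none of the 15 passed in limma (6 at an unadjusted p under 0.05). Of these 6, CES1 rose (0.19), while ABCC2 (-0.29), TKT (-0.22), FTL (-0.16), NQO1 (-0.12) and AKR1B10 (-0.09) fell. The data therefore argue against a rise shared by the 15, while the 4 genes were picked because they rose.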
